A study of Mus musculus with 20 samples.

How the data were processed

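Polyadenylated RNA of 20 fetal mouse livers was sequenced, 10 from control and 10 from nutrient-restricted pregnancies, with 2 male littermates from each of 5 litters per group. Per the labels' protocols, frozen tissue was ground, RNA was extracted with TRIzol and a column kit with DNase treatment, and all libraries were made with 1 strand-preserving kit at 1 sequencing centre. No batch or sequencing date is given in the labels. The deposited values used here are whole-number counts per transcript, in 1 table per fetus, not normalised and listing only transcripts with a count. Per the submitters' processing notes, FastQC, Bowtie2, DESeq2 and edgeR were used with the mouse genome build mm9, and the transcript names in the tables are those of the Ensembl gene set of that build. The counting tool, the tool versions, the treatment of reads that match several places and the use of strand are not given in the sources used here. Values of paralogs and of overlapping genes are therefore uncertain where the text says that they share sequence.

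A deposited gene table of the whole series was compared with these counts and was not used as expression. For 99.7% of genes in each fetus its value equals the sum, over the gene's transcripts, of the rank of the transcript's count among the distinct counts of that fetus sorted as text. It equals the summed counts for 8.52% to 9.66% of genes. All 20 of its columns were matched to fetuses by the names in the labels.

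Transcript counts were summed per gene with the annotation of the same build (NCBIM37, GENCODE release M1), which also gave gene names, coordinates and overlapping exons. Transcripts that matched no gene held 0.0788% to 0.154% of the counts of a fetus and were left out. Before this step the counts of a fetus totalled 14925778 to 28016953, and after it 21139 to 22268 genes had at least a single count. No pair of fetuses of a group had identical values, and each pair differed by more than sampling noise (chi-square over degrees of freedom 9.12 to 73.0 for 90 pairs), so none was counted as a repeat of another. This comparison cannot tell repeated libraries of a single animal from libraries of separate animals.

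The diet was given to the dam, so counts were summed over the 2 littermates and the 5 control and 5 MNR litters were compared. Genes were filtered with filterByExpr (minimum count 10), scaled with TMM, and tested with edgeR's quasi-likelihood test (two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. CPM values of litters use TMM-scaled library sizes, and CPM values of single fetuses, given for the sex-linked and the pancreatic transcripts, use unscaled totals of the gene counts. Log2 CPM values for correlations, distances and components use a prior count of 2. Of 51 gene lists fixed in advance, 49 with at least 5 tested members that were not used to check the sex were tested with limma's camera on voom values of the litter sums, with a preset correlation of 0.01, and with Benjamini-Hochberg adjustment over the lists. Of their 1006 genes, 13 were found under another symbol and 7 could not be matched. Camera with an estimated correlation and fry were run beside it. The similarity of littermates was tested by permuting litter labels within groups, and the distance between litters by exact permutation of 10 litters into 5 and 5.

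Genes named in the text follow a rule fixed before the data were examined. Among genes past the threshold with a mean of at least 1 CPM, the rule takes the 12 with the largest rise, the 12 with the largest fall, and of the rest the 5 with the smallest p in each direction, passing over predicted or clone-based names. For each list described, up to 4 members of smallest p are named, and some are not reported here. Igf1, Igf2, Igfbp1, Igfbp2, Alb, Afp, Pck1, G6pc, Fgf21, Cdkn1c, H19 and the sex-linked Xist, Ddx3y, Eif2s3y and Kdm5d are given whatever their result. Thra, Arntl and Clock were added after the values were seen, and so were the pancreatic transcripts named in the closing part.

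The edgeR procedure was tested on simulated counts drawn from the means and library sizes of these litters, with 200 of 17573 genes changed. It recovered 67 of 100 genes changed 1.5-fold and 98 of 100 changed 2-fold, with 175 calls of which 10 were false. A list shifted on purpose was called and 0 other lists were. The simulated genes varied independently of each other, so this cannot show how often camera calls lists falsely when genes are correlated.

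Alternatives fixed before the data were examined were the fetuses as separate libraries, the litter as a random effect in limma-voom, a single fetus per litter, litter means in limma-trend, DESeq2, 3 other scalings, looser and stricter filters and thresholds, the litter letter as a block, the erythroid marker level as a covariate, removal of the 20 most abundant genes, and leaving out each litter. Alternatives chosen after seeing the data were removal of the 3 fetuses with pancreatic transcripts, protein-coding genes alone, the gene table of the series read as counts, and the exact permutation of the litter means of each list. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pyranges 0.1.4 and matplotlib 3.10.9.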

Results

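Messenger RNA was profiled in the right liver lobe of 20 male fetuses of the outbred CD-1 mouse strain at embryonic day 18.5, shortly before birth. Of these, 10 fetuses came from control dams and 10 from dams under maternal nutrient restriction (MNR). Each group held 5 litters with 2 male littermates each, and a fetus is named here by its group, litter letter and number. A control litter and an MNR litter with the same letter come from different dams. The deposited transcript counts totalled 14925778 to 28016953 per fetus, with a median of 19658940. Control fetuses had 14925778 to 27848100 counts and MNR fetuses 16703824 to 28016953. Counts were summed over littermates, because the diet was given to the dam and the litter is then the replicate. In all, 17573 genes were tested with 5 litters per group. Unless stated otherwise, values are CPM (counts scaled by library size) as mean ± SD over 5 litters, changes are log2 fold changes of MNR over control with their standard error (SE), and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all tested genes.

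Transcripts of the Y chromosome were abundant in every fetus, as the sex of the animals requires, with CPM values here on unscaled totals per fetus. Ddx3y, a Y-linked RNA helicase, lay between 62.9 and 97.1 CPM in the 20 fetuses, Eif2s3y between 35.6 and 49.7 CPM, and Kdm5d between 18.6 and 25.6 CPM. Xist, the RNA that silences an X chromosome in females, lay between 0.114 and 0.708 CPM.

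Littermates resembled each other more than other fetuses of their group did. After each gene was centred on its group mean, the mean Pearson correlation across 17573 genes was 0.156 between the fetuses of a litter and -0.143 between fetuses of different litters of the same group. Centring on the group mean itself pulls correlations within a group below 0, so the difference is read rather than the sign. The difference of 0.299 exceeded that of relabelled litters (one-sided permutation test, 100000 resamples, p = 2e-05). All 10 littermate pairs, at 0.0167 to 0.269, lay above the mean of the other pairs. The litters of the MNR group were about as far from each other as the control litters were. The mean distance between litters was 51.4 in MNR and 52.9 in control on the log2 CPM scale, a difference of -1.53 (two-sided exact permutation test, 5 litters against 5, p = 0.675). The first principal component of the 20 profiles held 19.1% of the variance and separated the litter means of the groups by 28.3 units (two-sided exact permutation test, 5 litters against 5, p = 0.0238). The highest control fetus, B_1, lay at 19.2 on this component and its littermate B_2 at 3.21, while the lowest MNR fetus, D_1, lay at -3.93.

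**Figure D1:**
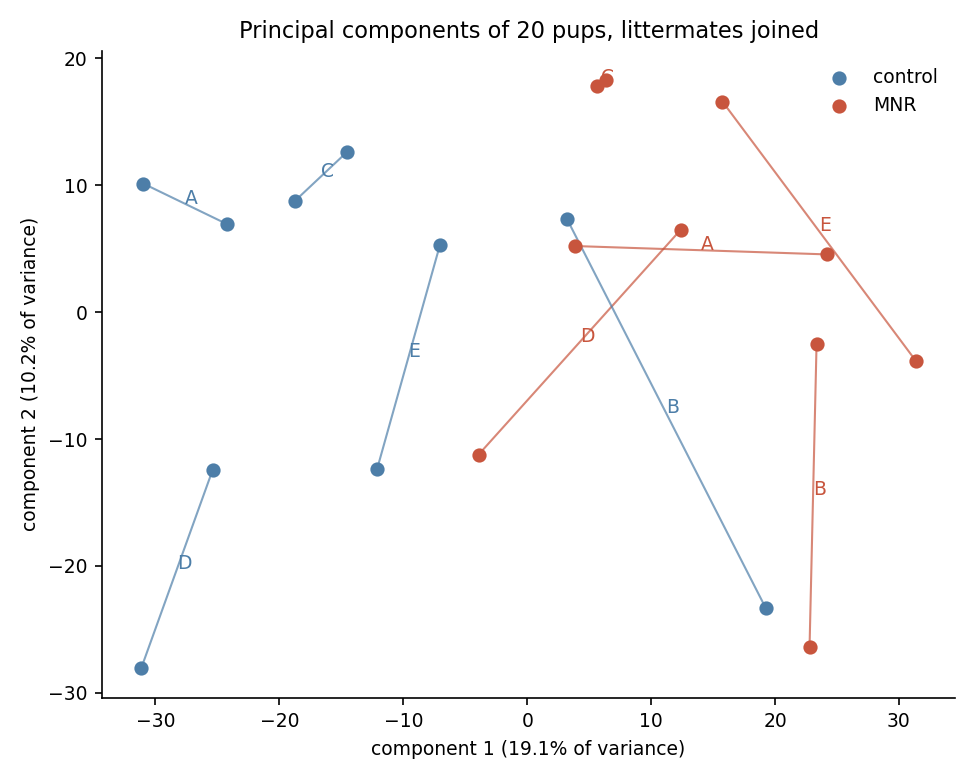
Principal components of the 20 fetal liver profiles, computed from log2 CPM of the 17573 tested genes. The horizontal axis is component 1 (19.1% of variance) and the vertical axis component 2 (10.2% of variance), points are fetuses coloured by group, and lines join littermates. Control fetuses spread from -31.2 to 19.2 on component 1 and MNR fetuses from -3.93 to 31.4.

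Fetal livers of the MNR group had less mRNA of the lipid synthesis genes Scd1, Scd2 and Fasn, and more of the circadian repressors Nr1d1 and Nr1d2 and of Gls2 and Hal, enzymes of amino acid breakdown. Nr1d1 rose 5.62-fold, from 1.40 ± 0.523 to 7.79 ± 2.17 CPM, and Scd1, the stearoyl-CoA desaturase of adult liver, fell from 263 ± 77.2 to 91.6 ± 22.7 CPM. Fasn, which encodes fatty acid synthase, fell from 269 ± 58.3 to 119 ± 34.5 CPM. In all, 117 of 17573 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 73 of them higher and 44 lower in MNR. Of the 117 genes, 108 were protein coding, 13 had only a predicted or clone-based name, and 5 had a mean under 1 CPM. The litters of the groups did not overlap for 109 of the 117 genes. Over all genes tested they did not overlap for 791 of 17573. Chance gives 0.794% of genes as an average over all splits of the litters. Where genes are correlated a single split can lie far from this average, and the spread of the count over splits was not computed. With upper-quartile scaling 178 genes passed, of which 38.2% were higher in MNR, against 62.4% under the trimmed-mean scaling (TMM) used throughout.

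The number of genes past the threshold rested on single litters. Without control litter A, C or E, or without MNR litter B or E, 0 genes passed in edgeR, the only tool run on these subsets. Without control litter D 2 genes passed, without MNR litter A 2, and without MNR litter C 30, whereas 843 passed without control litter B and 512 without MNR litter D. Over these 10 fits 2818 to 4139 genes had an unadjusted p under 0.05, against 3452 with all litters. All 117 genes kept their direction in each of the 10 fits, but 0 of them passed in all 10. With only fetus 1 of each litter 0 genes passed in edgeR, where 1699 had an unadjusted p under 0.05, and with only fetus 2 of each litter 499 passed. DESeq2 called 1163 genes on the same litter sums.

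The circadian repressors Nr1d1 and Nr1d2 and the clock output factor Tef rose in MNR livers. Nr1d1, which encodes the nuclear receptor REV-ERB alpha and lies on the minus strand of chromosome 11 at 98629246 to 98636647 (mm9), rose by a log2 fold change of 2.49 (SE 0.27, edgeR adjusted p = 0.018). Nr1d2, its paralog on chromosome 14 at 19036568 to 19071641, rose by 1.30 (SE 0.19, edgeR adjusted p = 0.0257), from 8.52 ± 2.27 to 20.9 ± 4.0 CPM. Tef, a transcription factor of the clock output on chromosome 15 at 81632851 to 81657291, rose by 0.80 (SE 0.10, edgeR adjusted p = 0.0257), from 39.4 ± 3.48 to 68.5 ± 9.98 CPM. Every MNR litter lay above every control litter for these 3 genes. Of the 18 clock genes of the list fixed in advance, 3 rose and 15 did not pass over all genes, while 12 higher and 2 lower members passed when adjusted over the list alone. The lower members were Npas2, a partner of the clock activator Arntl, at a log2 fold change of -0.73 (edgeR adjusted p = 0.0564 over all genes), and Arntl itself at -0.27 (edgeR adjusted p = 0.139). Adjustment over a list alone, here and below, does not correct for the number of lists tested. Among all 17573 genes, 3452 had an unadjusted edgeR p under 0.05, so passing over a list alone is a weak criterion. The median change of the clock list was 0.30. The list passed in limma's camera test with a preset correlation (adjusted p = 0.00027), with an adjusted p = 0.418 with an estimated correlation. The mean of the list per litter gave an exact permutation p = 0.0238. This p is unadjusted, as are those of the lists below unless called adjusted, and the lowest adjusted exact permutation p of any list was 0.106. The exons of Nr1d1 overlap those of Thra on the opposite strand, and Thra stood at 26.4 ± 1.95 CPM in control and 29.5 ± 1.26 CPM in MNR (log2 fold change 0.16, edgeR adjusted p = 0.164). The exons of Tef overlap the predicted gene Gm17597 on the opposite strand.

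The stearoyl-CoA desaturases, which make monounsaturated fatty acids, and Fasn, Srebf1 and Pnpla3 of lipid synthesis fell in MNR livers. Scd1 fell by 1.52 (SE 0.23, edgeR adjusted p = 0.0262) and Scd2, the most abundant desaturase in these livers, fell by 1.29 (SE 0.22, edgeR adjusted p = 0.0345), from 803 ± 208 to 329 ± 104 CPM. Scd3 fell by 1.2 and Scd4 fell by 1.08 (edgeR adjusted p = 0.0286 and 0.0262). These 4 genes lie side by side on chromosome 19 (mm9), from the start of Scd3 at 44277759 to the end of Scd1 at 44482199. They are close paralogs, and the treatment of reads that match several genes is not given in the sources used here, so reads of the abundant Scd1 and Scd2 can add to the values of Scd3 and Scd4. Scd2 also shares exon sequence with AC123853.2 on the same strand. Fasn on chromosome 11, at 120667254 to 120685492, fell by 1.17 (SE 0.21, edgeR adjusted p = 0.0374). Srebf1, which encodes a transcription factor that drives lipid synthesis, fell by 0.71 (SE 0.13, edgeR adjusted p = 0.0436), from 178 ± 19.7 to 109 ± 23.7 CPM, and shares exon sequence with Rai1 on the opposite strand. Pnpla3, a lipid droplet protein, fell by 1.35 (SE 0.26, edgeR adjusted p = 0.044), from 36.9 ± 14.0 to 14.4 ± 4.94 CPM.

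Of the 21 tested genes of fatty acid and triglyceride synthesis, 5 fell and 16 did not pass over all genes, and 16 lower and 1 higher passed when adjusted over the list alone. The median change was -0.45. With the preset correlation camera called the list (adjusted p = 4.31e-10), with an adjusted p = 0.418 with an estimated correlation. The list mean of every MNR litter lay below that of every control litter (exact permutation p = 0.00794, the smallest that 5 litters against 5 allow). Acsl3, which activates long-chain fatty acids, fell by 0.72 (SE 0.11, edgeR adjusted p = 0.0262) and shares exon sequence with Utp14b on the same strand. The markers of mature hepatocytes moved little, with a median change of 0.08 over 23 genes (camera adjusted p = 0.17, and adjusted p = 0.761 with an estimated correlation). Srebf1, Pnpla3 and Mvd did not pass when the mean level of erythroid markers per litter entered the edgeR model.

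The tested cholesterol synthesis genes lay lower in MNR livers. Hmgcs1 could not be matched and was not among them. All 23 tested genes had a negative log2 fold change, with a median of -0.52. Mvd, the mevalonate decarboxylase on chromosome 8 at 124957496 to 124967322, fell by 0.97 (SE 0.18, edgeR adjusted p = 0.0416), from 21.7 ± 4.63 to 11.1 ± 2.82 CPM. The other 22 did not pass over all genes, and 22 of the 23 passed as lower when adjusted over the list alone. Cyp51 and Dhcr7 had log2 fold changes of -0.72 and -0.71 (edgeR adjusted p = 0.0537 and 0.0564). Camera with the preset correlation called it (adjusted p = 7.17e-15), with an adjusted p = 0.418 with an estimated correlation, and the exact permutation p of its litter means was 0.0159.

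**Figure D2:**
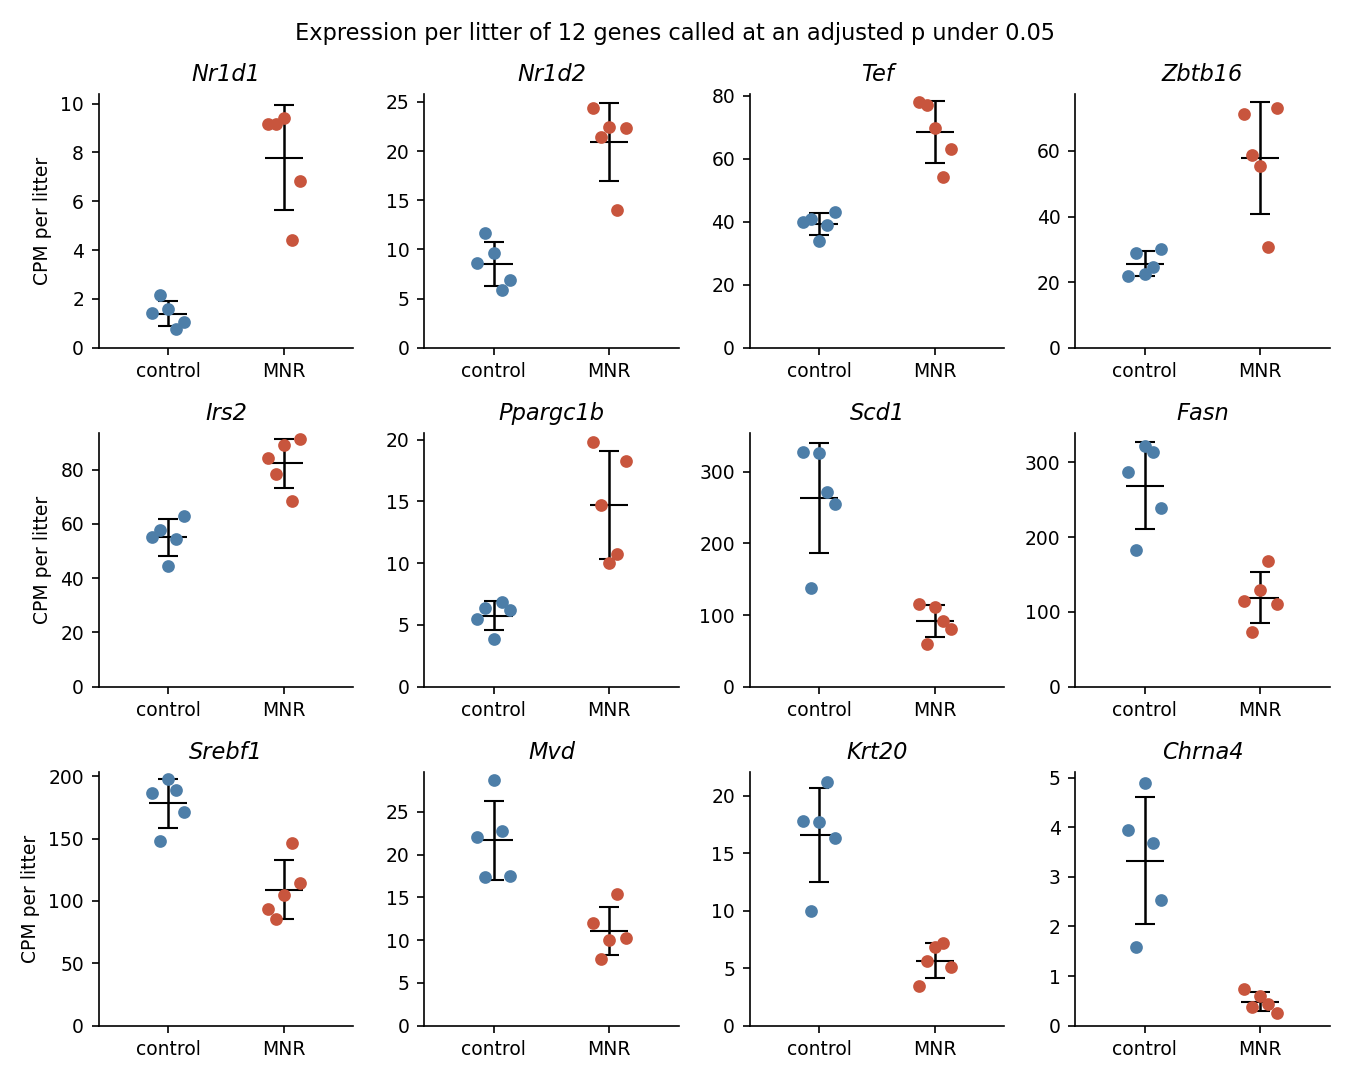
CPM of 12 genes in the 5 control and 5 MNR litters, on a linear vertical axis for each gene. Points are litter sums, and the horizontal line and bar give the mean ± SD of 5 litters. Nr1d1 rises from 1.40 to 7.79 CPM and Scd1 drops from 263 to 91.6 CPM, with no overlap between the litters of the groups.

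The list of targets of the fasting-activated FOXO transcription factors and of fasting genes, here the FOXO list, held 21 genes, Foxo1 itself among them. A positive log2 fold change was found for 20 of them, with a median of 0.56. Of these 21 genes, 1 rose and 20 did not pass over all genes, and 15 passed as higher when adjusted over the list alone. The list passed camera with the preset correlation (adjusted p = 4.31e-10), with an adjusted p = 0.418 with an estimated correlation, and an exact permutation p = 0.0159 for its litter means. Irs2, an insulin receptor substrate that FOXO factors induce, rose by 0.58 (SE 0.10, edgeR adjusted p = 0.0331), from 55.0 ± 6.79 to 82.2 ± 9.08 CPM. Among those that did not pass over all genes, Ccng2 stood at 23.5 ± 4.04 CPM in control and 36.8 ± 7.29 CPM in MNR (log2 fold change 0.65, edgeR adjusted p = 0.0587), and Foxo1 and Angptl4 had log2 fold changes of 0.45 and 0.77 (edgeR adjusted p = 0.0587 and 0.0664). Irs2 overlaps the unnamed transcript 9530052E02Rik on the opposite strand.

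Of 23 tested glucocorticoid receptor targets, 21 had a positive log2 fold change, with a median of 0.42. Over all genes 1 rose and 22 did not pass, and 11 passed as higher when adjusted over the list alone. In camera with a preset correlation the list passed (adjusted p = 9.56e-09), with an adjusted p = 0.418 with an estimated correlation, and an exact permutation p = 0.0159. Zbtb16, a zinc finger transcription factor that glucocorticoids induce, lies on chromosome 9 at 48462416 to 48644050 and rose by 1.18 (SE 0.20, edgeR adjusted p = 0.032), from 25.6 ± 3.72 to 57.9 ± 17.0 CPM. Ddit4, an inhibitor of mTORC1 signalling, had a log2 fold change of 1.33 (edgeR adjusted p = 0.0602), and Gadd45b and Tsc22d3 had 0.72 and 0.64 (edgeR adjusted p = 0.0587 and 0.0618). The list shares 4 genes with the FOXO list.

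Gls2 and Hal of amino acid breakdown, Gpt of gluconeogenesis and Arg1 of the urea cycle rose in MNR livers. Gls2, the liver glutaminase, rose by 0.45 (SE 0.06, edgeR adjusted p = 0.0257), from 59.6 ± 2.30 to 81.6 ± 7.03 CPM. Hal, histidine ammonia-lyase, rose by 0.58 (SE 0.11, edgeR adjusted p = 0.0454), but did not pass with the erythroid marker level in the model. Arg1, the arginase that ends the urea cycle, rose by 0.60 (SE 0.09, edgeR adjusted p = 0.0257), from 448 ± 37.6 to 678 ± 74.3 CPM. Gpt, alanine aminotransferase, rose by 0.92 (SE 0.18, edgeR adjusted p = 0.0437), from 6.59 ± 2.18 to 12.5 ± 0.857 CPM. The cytosolic aspartate aminotransferase Got1 and the urea cycle enzyme Asl had log2 fold changes of 0.83 and 0.47 (edgeR adjusted p = 0.0576 and 0.0582). The transcriptional coactivator Ppargc1a had a log2 fold change of 0.78 (edgeR adjusted p = 0.0904), and its relative Ppargc1b rose by 1.35 (SE 0.21, edgeR adjusted p = 0.0263). Gls2 overlaps Spryd4 on the opposite strand.

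Of the 32 genes of amino acid breakdown, 2 rose over all genes and 5 passed as higher when adjusted over the list alone. Of the 18 genes of gluconeogenesis, 1 rose over all genes and 6 passed as higher when adjusted over the list alone. Of the 8 urea cycle genes, 1 rose over all genes and 2 passed as higher when adjusted over the list alone. In camera with a preset correlation these 3 lists passed with adjusted p = 5.92e-05, 0.000147 and 0.0197, with adjusted p = 0.42, 0.418 and 0.504 with an estimated correlation. Their exact permutation p-values were 0.0238, 0.0238 and 0.00794. The median changes were 0.24, 0.24 and 0.18. The urea cycle list no longer passed camera without control litter D (adjusted p = 0.0655). Pck1 and G6pc, main enzymes of glucose release, did not pass, with log2 fold changes of 0.63 (SE 0.49, edgeR adjusted p = 0.515) for Pck1 and 0.31 (SE 0.28, edgeR adjusted p = 0.579) for G6pc.

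A list of 30 genes joined fatty acid oxidation, ketogenesis and targets of the nuclear receptor PPAR alpha, and its median change was 0.08. Of these genes 0 passed over all genes in edgeR and 6 passed as higher when adjusted over the list alone. Pdk4, a kinase that restrains glucose oxidation, stood at 53.7 ± 17.6 CPM in control and 91.1 ± 18.8 CPM in MNR (log2 fold change 0.76, edgeR adjusted p = 0.0908). Cpt1a, which admits fatty acids to mitochondria, had a log2 fold change of 0.42 (edgeR adjusted p = 0.0987). With the preset correlation camera called the list (adjusted p = 0.00884), with an adjusted p = 0.727 with an estimated correlation and an exact permutation p = 0.183. Without control litter D it no longer passed camera (adjusted p = 0.0938).

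Genes of the unfolded protein response of the endoplasmic reticulum lay lower in MNR livers. Of 20 genes 18 had a negative log2 fold change, with a median of -0.29. None passed over all genes in edgeR, while 12 lower and 1 higher passed when adjusted over the list alone. The chaperone Dnajb11 had a log2 fold change of -0.35 and the transcription factor Xbp1 one of -0.31 (edgeR adjusted p = 0.0721 and 0.0819). Camera with the preset correlation called it (adjusted p = 2.02e-06), with an adjusted p = 0.42 with an estimated correlation and an exact permutation p = 0.0317. Targets of the amino acid response factor ATF4 went both ways. Cebpb rose by 0.49 (SE 0.08, edgeR adjusted p = 0.0286) and overlaps Tmem189 on the opposite strand. The cysteine-producing enzyme Cth had a log2 fold change of 0.78 and the cysteinyl-tRNA synthetase Cars one of -0.50 (edgeR adjusted p = 0.0526 and 0.0515). Over the list alone 4 ATF4 targets passed as higher and 8 as lower, and the list did not pass camera (adjusted p = 0.273, and adjusted p = 0.761 with an estimated correlation).

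Hypoxia-inducible genes lay higher in MNR livers, with 22 of 24 members above 0 and a median change of 0.29. None passed over all genes in edgeR and 10 passed as higher when adjusted over the list alone. Pfkfb3, which promotes glycolysis, stood at 41.4 ± 9.71 CPM in control and 75.1 ± 20.6 CPM in MNR (log2 fold change 0.86, edgeR adjusted p = 0.0704). Ddit4 belongs to this list as well. The list as a whole passed camera with the preset correlation (adjusted p = 9.07e-07), with an adjusted p = 0.462 with an estimated correlation and an exact permutation p = 0.0635.

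Among markers of the blood cells that the fetal liver produces, all 18 megakaryocyte and platelet genes had a positive log2 fold change, with a median of 0.26, and 0 of them passed over all genes in edgeR. Gp9, a platelet glycoprotein, had a log2 fold change of 0.29 and Rab27b one of 0.35 (edgeR adjusted p = 0.0731 and 0.074). Neutrophil granule genes had a median of 0.27, with Gfi1 at 0.44 and Ctsg at 0.29 (edgeR adjusted p = 0.0643 and 0.074). Over the lists alone 11 megakaryocyte and 8 neutrophil genes passed as higher, and 0 of either list passed over all genes in edgeR. Both lists passed in camera with a preset correlation (adjusted p = 2.45e-08 and 7.23e-08), with adjusted p = 0.418 and 0.462 with an estimated correlation and exact permutation p-values of 0.0159 and 0.0317. Spic, a transcription factor of iron-recycling macrophages, rose by 0.53 (SE 0.08, edgeR adjusted p = 0.0257), from 9.70 ± 0.702 to 14.0 ± 1.15 CPM. Hmox1, the heme oxygenase of the same cells, had a log2 fold change of 0.48 (edgeR adjusted p = 0.0645). The macrophage list, in which 1 of 19 genes rose over all genes and 2 passed over the list alone, had a median of 0.12 (camera adjusted p = 0.00385, adjusted p = 0.571 with an estimated correlation, exact permutation p = 0.0794).

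Neither lymphoid nor erythroid markers had a member past the threshold, over all genes in edgeR or when adjusted over the list alone. Of 15 tested lymphoid genes 13 had a negative log2 fold change, with a median of -0.32 (camera adjusted p = 0.00511, adjusted p = 0.727 with an estimated correlation, exact permutation p = 0.175). The B cell gene Cd79a had a log2 fold change of -0.55 (edgeR adjusted p = 0.161). Without control litter A the lymphoid list no longer passed camera (adjusted p = 0.0838). The 27 tested erythroid markers had a median of -0.10 (camera adjusted p = 0.0989, adjusted p = 0.833 with an estimated correlation). Kit, a receptor of blood progenitors and mast cells, had a log2 fold change of 0.45 (edgeR adjusted p = 0.0569). Markers of stellate cells, fibroblasts and matrix had a median of -0.19 over 23 genes, of which 0 passed over all genes in edgeR and 2 passed as lower over the list alone, namely Lhx2 at -0.43 and Pdgfrb at -0.32 (edgeR adjusted p = 0.072 and 0.0946 over all genes). This list passed in camera with a preset correlation (adjusted p = 0.00141), with an adjusted p = 0.571 with an estimated correlation and an exact permutation p = 0.0556.

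Cytosolic ribosomal protein genes, mitotic genes, mitochondrially encoded genes and immediate early genes passed camera with the preset correlation. With an estimated correlation their adjusted p-values were 0.761, 0.761, 0.754 and 0.632, and their exact permutation p-values were 0.278, 0.437, 0.135 and 0.365. No gene of the ribosomal, mitotic and mitochondrial lists passed over all genes in edgeR or when adjusted over the list alone, and of the immediate early genes 1 rose over all genes and 4 passed as higher over the list alone. Ribosomal protein genes lay above 0 for 42 of 43 members, with a median of 0.07 (camera adjusted p = 0.00268). The 13 mitochondrially encoded genes all lay below 0, with a median of -0.11 (camera adjusted p = 0.0447). Genes of mitosis and G2/M had a median of -0.11 over 27 members, with Plk1, a mitotic kinase, at -0.20 (camera adjusted p = 0.0197). Immediate early genes had a median of 0.16 over 17 members (camera adjusted p = 0.0287). They went both ways, with log2 fold changes from -1.26 to 0.62, and the lowest did not pass (edgeR adjusted p = 0.194). Their member Btg2, an inhibitor of proliferation, rose by 0.54 (SE 0.10, edgeR adjusted p = 0.0436) without passing when the erythroid marker level entered the model. Without control litter A the ribosomal list had a camera adjusted p = 0.142, without control litter B the mitochondrial list 0.179, without control litter D the mitotic list 0.6, and without MNR litter D the immediate early list 0.226.

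In all, 20 of 49 gene lists passed camera with the preset correlation of 0.01, 13 of them higher and 7 lower in MNR. Other splits of the same litters, tried after the data were seen, called a median of 15 lists in this test. Its small adjusted p-values are therefore not to be taken at face value. With an estimated correlation 0 lists passed in camera, and the estimated correlation gave the highest adjusted p among 17 camera and fry alternatives for each of the 20 lists. limma's fry, which tests whether the members of a list move on balance in one direction, called 8 lists, 6 of them among the 20. An exact permutation of the litter means of each list gave an unadjusted p under 0.05 for 14 of 49 lists, 11 of them among the 20, and 0 lists passed after adjustment (lowest adjusted p = 0.106).

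**Figure D3:**
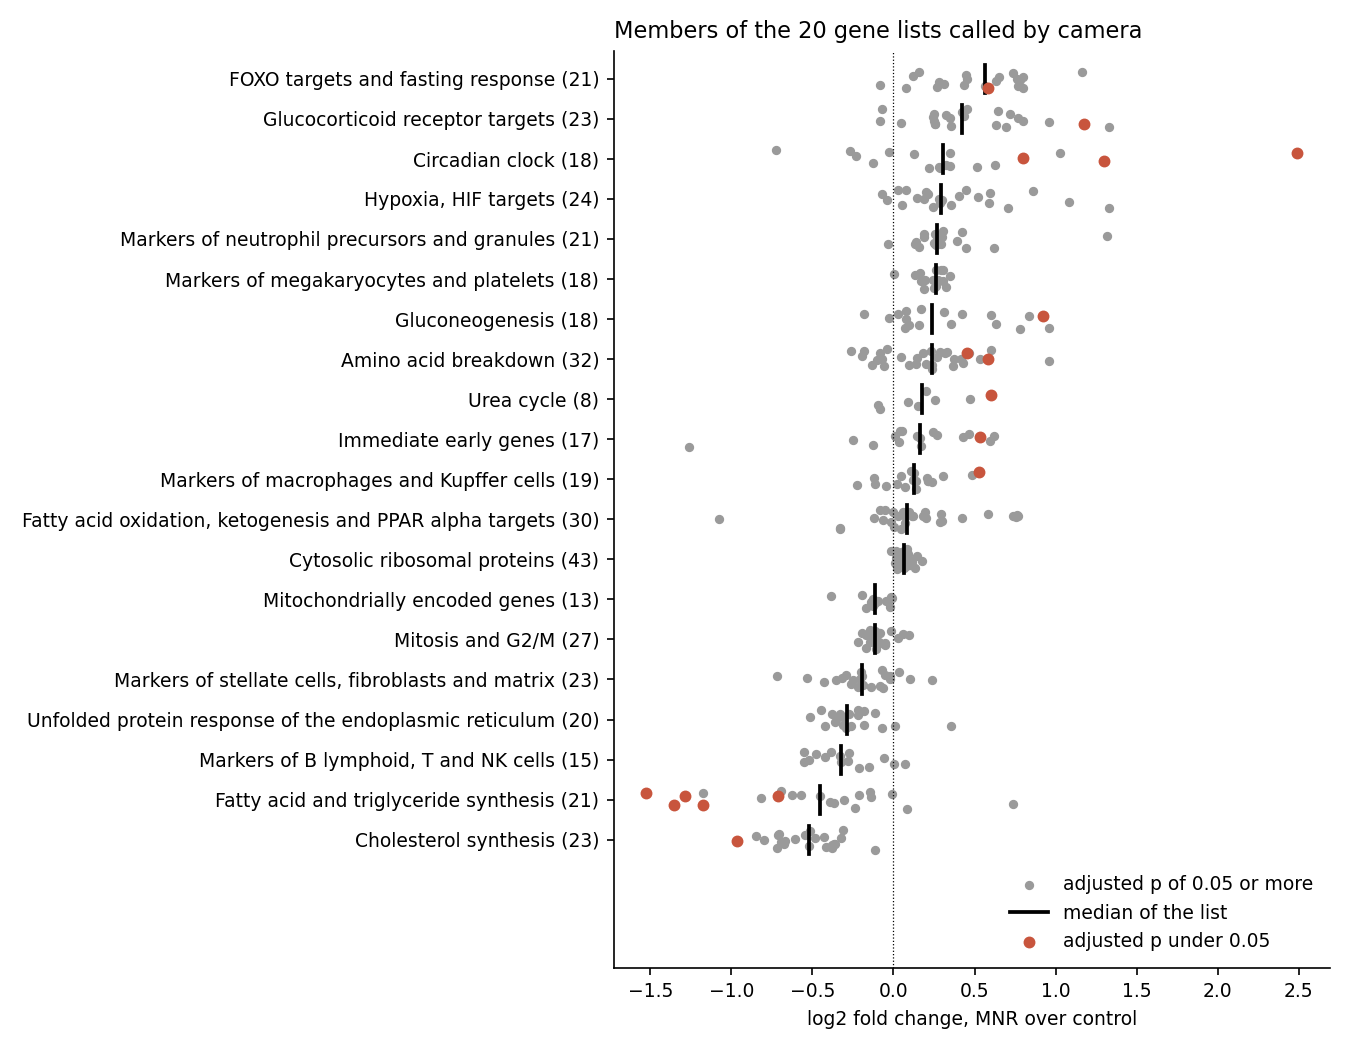
Log2 fold changes of the members of the 20 gene lists that passed camera with the preset correlation. Each point is a gene, red points passed an edgeR adjusted p of 0.05 over all genes, and the line marks the median of each list. Cholesterol synthesis has the lowest median, at -0.52, and the FOXO list the highest, at 0.56.

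Named genes outside the lists fell as well. Chrna4, the alpha 4 subunit of the nicotinic acetylcholine receptor, lies on chromosome 2 at 180753085 to 180778251 and fell by 2.77 (SE 0.33, edgeR adjusted p = 0.0215), from 3.33 ± 1.29 to 0.483 ± 0.190 CPM. Krt20, a keratin of epithelia on chromosome 11 at 99289717 to 99299464, fell by 1.55 (SE 0.21, edgeR adjusted p = 0.0257), from 16.6 ± 4.11 to 5.65 ± 1.5 CPM. The neighbouring beta-tubulin genes Tubb2a and Tubb2b on chromosome 13 fell by 1.16 and 1.11 (edgeR adjusted p = 0.0412 and 0.0286). They are close paralogs, so their reads can be shared. The kinesin Kif12 and the tight junction protein Cldn2 fell by 1.28 and 1.24 (edgeR adjusted p = 0.034 and 0.0416). Pth1r, the parathyroid hormone receptor, fell by 0.89, and the collagen chaperone Serpinh1 fell by 0.43 (edgeR adjusted p = 0.0286 for both). Cisd2, an iron-sulfur protein of the endoplasmic reticulum and mitochondria, fell by 0.31 (edgeR adjusted p = 0.0286), and Ncrna00085, which shares sequence with Mir125a on the same strand, fell by 0.94 (edgeR adjusted p = 0.0257).

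Among the named genes that rose, Rasd2, a small GTPase, had the largest change after Nr1d1, at a log2 fold change of 2.13 (SE 0.41, edgeR adjusted p = 0.0454), from 2.24 ± 1.62 to 9.68 ± 3.56 CPM. The litters of the groups overlapped for Rasd2 and for the transcription factor Klf5, which rose by 0.99 (edgeR adjusted p = 0.0456) but did not pass with the erythroid marker level in the model. Cd83, an immune cell surface protein, rose by 1.51, and the guanylate cyclase receptor Gucy2c rose by 0.80 (edgeR adjusted p = 0.0257 and 0.0286). The small GTPase Arl4d rose by 1.13 and the kinase Pim3 rose by 1.0 (edgeR adjusted p = 0.0286 and 0.0347). Fam134b, a receptor for autophagy of the endoplasmic reticulum, rose by 0.97 (edgeR adjusted p = 0.0416). Fbxo31, a ubiquitin ligase subunit, and the membrane protein Tmem219 rose by 0.55 and 0.45 (edgeR adjusted p = 0.0257 for both).

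Genes of fetal growth and liver identity that were fixed for reporting whatever their result did not pass the test. Igf1 stood at 36.9 ± 7.79 CPM in control and 27.0 ± 3.19 CPM in MNR, a log2 fold change of -0.45 (SE 0.13, edgeR adjusted p = 0.0987). Igfbp1, a binding protein that limits insulin-like growth factor action, stood at 1830 ± 755 and 3184 ± 951 CPM, a log2 fold change of 0.80 (SE 0.28, edgeR adjusted p = 0.153). The imprinted growth genes Igf2, H19 and Cdkn1c had log2 fold changes of 0.03 (SE 0.09), 0.08 (SE 0.09) and 0.02 (SE 0.39), and Igfbp2 had 0.13 (SE 0.32). The values of Igf2, Cdkn1c and Igfbp2 turned negative when single litters were left out, and that of Cdkn1c reached -0.25 without MNR litter D. Alb, the albumin gene, had -0.03 (SE 0.09, edgeR adjusted p = 0.905), which turned to 0.01 without control litter E or MNR litter A, and Afp, alpha-fetoprotein, -0.24 (SE 0.14, edgeR adjusted p = 0.361). Fgf21, a fasting hormone of the liver, stood at 1.53 ± 2.02 and 0.728 ± 0.715 CPM (log2 fold change -1.08, SE 0.83, edgeR adjusted p = 0.511). The control mean rested on litter C, at 5.06 CPM against 0.298 to 1.40 CPM in the other control litters, and without it the log2 fold change turned to 0.19.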

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

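The tests of how many splits of the litters give as many genes or lists were chosen only after those counts were seen, as were the removal of the 3 fetuses with pancreatic transcripts and the margin taken from littermates in the test of exchanged labels.

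The groups checked were the control or MNR litters of each named gene, and the fetuses for library totals and Cpa1. In 13 of 190 groups (6.84%) a sample lay far from the rest, and the values in parentheses are its gap to the nearest sample as a share of the range. Chance gives about 1 in 20. The tally cannot be judged against that share, because it includes Thra, Cela1 and Cpa1, added after their values were seen. MNR litter D lay apart for Nr1d2, at 14.0 CPM against 21.4 to 24.3 (0.716), for Pnpla3, at 23.0 CPM against 10.7 to 13.9 (0.736), and for Ppargc1a, at 17.98 CPM against 32.9 to 35.3 (0.857). Control litter B lay apart for Dhcr7, at 55.3 CPM against 91.1 to 97.3 (0.853), for Thra, at 29.7 CPM against 24.6 to 26.1 (0.714), and for the elastase gene Cela1, at 20.5 CPM against 7.06 to 10.4 (0.753). Control litter C lay apart for Tmem219, at 10.1 CPM against 11.3 to 11.6 (0.747), for Pth1r, at 7.76 CPM against 5.53 to 6.11 (0.742), and for Fgf21, at 5.06 CPM against 0.298 to 1.40 (0.769). MNR litter A lay apart for Got1, at 283 CPM against 149 to 180 (0.770), and MNR litter C for Igf2, at 6411 CPM against 5196 to 5470 (0.775). On unscaled totals per fetus, Cpa1, a pancreatic carboxypeptidase, reached 29.2 CPM in control fetus B_1 against 0.148 to 1.11 in the other control fetuses (0.967), and 13.9 CPM in MNR fetus B_1 against 0.0513 to 6.90 in the other MNR fetuses (0.504).

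Control litter B and MNR litter D lay towards the other group. On the 500 genes of smallest p among the other 8 litters, with 0 at the control mean and 1 at the MNR mean, control litter B lay at 0.529 and MNR litter D at 0.493, a difference of -0.0363, while the other 24 pairs of a control and an MNR litter differed by 0.124 to 1.08. The pair had been picked because the split that exchanges it called 239 genes, so a low value was likely from the start. An exchange of the 2 labels was to put the difference below 0 and correct labels above 0.2. The value met the former bound, but by less than 0.274, the mean difference between littermates in these 2 litters alone. On the same scale control B_1 lay at 0.631 and B_2 at 0.430, and MNR D_1 at 0.359 and D_2 at 0.706. In each litter 1 fetus thus lay nearer to its own group and its littermate nearer to the other. Where control litter B was held out with another MNR litter it lay at 0.639 to 0.701, and MNR litter D with another control litter at 0.359 to 0.407, each nearer to the mean of the other group, but on a scale that the other litter of the pair helped to set. Since the difference between the 2 litters was smaller than that between their own littermates, exchanged labels cannot be told apart from litters that respond or vary in opposite ways. The latter stays untested. Control B_1 also held pancreatic transcripts, described next, and their part in its position was not tested. With both litters of this picked pair left out, 1148 genes passed in edgeR.

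Pancreatic transcripts stood out in 3 fetuses, control B_1, MNR B_1 and MNR E_1. The chymotrypsinogen gene Ctrb1 reached 206, 72.5 and 50.2 CPM (unscaled totals) there against a median of 0.104 CPM in the other 17 fetuses, and Ins1, Ins2 and Gcg were highest in the same 3. Of 8 other acinar genes, 7 (87.5%) had the same 3 highest fetuses as Cpa1, which is what pieces of pancreas taken with the lobe would give. A biological source within the liver was not tested. Without these 3 fetuses 215 genes passed, 110 of them among the 117.

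The rise of Nr1d1, Nr1d2 and Tef may come from livers taken at different times of day in the 2 groups, or from the diet. A shift of the whole clock was to bring the median change of Arntl, Npas2 and Clock below -0.3, and a difference without one was to leave it above -0.1. The median was -0.27, between the 2 bounds, with Npas2 at -0.73, Arntl at -0.27 and Clock at 0.13. No outcome could have told the 2 explanations apart, since a clock shifted by the diet would move these genes as another hour would. The hour of collection is not given in the sources used here.

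Of 100 splits of the 10 litters drawn from 126, 2 gave at least as many genes as the real 117, the real split included. The highest other count was 239, from the split that exchanges control litter B and MNR litter D, and 91 splits gave 0 genes in edgeR. Few splits thus reached the real count. Chance is not excluded as its source, because the test and its bound were chosen after the count was seen and another split gave more genes. For the lists, 26 of 100 splits gave at least the real 20, and the other splits gave a median of 15 and at most 32. Chance therefore cannot be excluded as the source of the number of lists called by camera.

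The lower values of lipid synthesis genes had also been set against a lower share of hepatocytes and against reads shared among the Scd paralogs. Those 2 tests were taken out of the weighing after their values were seen, and the values were a median of 0.08 over hepatocyte markers and 4 fallen lipid synthesis genes outside the Scd family.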

How the results depend on the processing

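Removal of the 3 fetuses with pancreatic transcripts, the restriction to protein-coding genes, the gene table of the series read as counts and the exact permutation of list means were chosen only after seeing the data, and the cause of a change was not tested unless the setting itself gives it.

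The count of differentially expressed genes, MNR against control, was 117, and the number of genes higher in MNR (73) and of genes lower in MNR (44) are given in this order for each setting that moved a count by over 1.5 times. The 20 fetuses as separate libraries gave 2301 genes (1227 higher and 1074 lower), which counts littermates as independent. limma-voom with the litter as a random effect gave 1088 (609 and 479), DESeq2 1163 (656 and 507, with 2047 adjusted p-values missing), litter means in limma-trend 202 (127 and 75), and fetus 2 of each litter alone 499 (282 and 217). Fetus 1 of each litter alone gave 0 in edgeR, with 1699 genes at an unadjusted p under 0.05, and no other tool was run on it. Upper-quartile scaling gave 178 genes, 110 of them lower, and a mean of at least 5 CPM gave 249 (144 and 105), where fewer genes were tested. An adjusted p under 0.1 gave 875 (495 and 380) and an added fold of at least 1.5 gave 64 (37 and 27). Without the 3 fetuses with pancreatic transcripts 215 genes passed (124 and 91), and the gene table of the series gave 0. Leaving out each litter gave 0 to 843 genes, 0 to 425 higher and 0 to 418 lower. DESeq2's size factors, library totals alone, no filter on low counts, the erythroid covariate, removal of the 20 most abundant genes and protein-coding genes alone gave 107 to 145 genes. A similar count did not mean the same genes, since the erythroid covariate gave 107 genes with 81 of them among the 117.

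Of the 41 named genes that passed, 41 passed in DESeq2, 41 with upper-quartile scaling, 35 with the erythroid covariate, 40 with fetus 2 alone and 0 with fetus 1 alone. Btg2 did not pass with library totals alone, Hal with litter means in limma-trend, and Klf5 with fetus 2 alone. When a litter was left out, 101 of 410 values stayed past the threshold and 309 did not, with 0 reversed. In the other settings 670 of 731 stayed past it and 0 reversed. Of the 52 named genes that did not pass, 42 of 520 values passed when a litter was left out and 188 of 920 did so in the other settings, with 0 of them past the threshold in the opposite direction. The sign alone, without a call, changed in 13 of the 520 values, for Fgf21, Cdkn1c, Igf2, Igfbp2, Alb and Kdm5d, and in 7 of the 920, for the same genes without Fgf21.

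Of the lists, 20 passed in camera with the preset correlation, 0 with an estimated correlation, 8 in fry (6 of them among the 20) and 0 in the exact permutation of list means, where 14 had an unadjusted p under 0.05. Leaving out each litter gave 18 to 23 lists, and 184 of 200 values of the 20 lists stayed past the threshold. The difference between littermates and other fetuses was 0.385 on the 1000 most variable genes and 0.285 with Spearman correlation, and the difference in distance between litters ranged from -3.50 to 1.49 when a litter was left out.

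With the litter letter as a block, 232 genes passed, 154 higher and 78 lower, 99 of them among the 117, and 19 lists passed in camera. The letters do not pair the litters by design. Litters of the same letter correlated at -0.00928 to 0.184, with 3 of 5 pairs over 0.1, and 4 of 10 litters correlated best with their own letter.

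Of the 117 genes, 5 had a mean under 1 CPM and rest on few counts, and how depth limits the calls was not tested.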

Other observations

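The reading of the series' gene table as counts and the exact permutations of list means were chosen only after the data were seen.

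Autophagy and lysosome genes did not pass camera (adjusted p = 0.081, and adjusted p = 0.418 with an estimated correlation), yet their litter means did not overlap between the groups (unadjusted exact permutation p = 0.00794, the smallest that 5 litters against 5 allow, adjusted p = 0.106). Of 49 lists, those of fatty acid and triglyceride synthesis and of the urea cycle reached this p as well. The difference of the autophagy and lysosome genes was small, with a median of 0.08 over 24 genes, and Gabarapl1 and Map1lc3b, which encode autophagosome proteins, had log2 fold changes of 0.44 and 0.18 (edgeR adjusted p = 0.115 and 0.125). Markers of blood stem and progenitor cells had a median of 0.04 (camera adjusted p = 0.101, exact permutation p = 0.0238) and p53 targets one of 0.03 (camera adjusted p = 0.349, exact permutation p = 0.0476). Glycolysis genes had a median of 0.14 (camera adjusted p = 0.084), with the hexokinase gene Hk2 at a log2 fold change of 0.71 (edgeR adjusted p = 0.0949). Imprinted genes of the fetal liver had a median of -0.02 (camera adjusted p = 0.83), and their member of smallest p, Mest, had a log2 fold change of -0.30 (edgeR adjusted p = 0.0701).

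The median, the mean and the camera direction differed in sign for 6 of 49 lists, of which 0 passed camera with either correlation. Heat shock genes had a median of -0.08 and a mean of 0.03, interferon response genes a median of -0.04 and a mean of 0.04, and camera placed both lower. Markers of pancreas and gut had a median of -0.24 and a mean of -0.09, and camera placed them higher. The other 3 were the lists of bile acid synthesis, of chromatin modifiers and of acute phase proteins.

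Read as counts, the deposited gene table of the series gave 0 of 20733 genes past the threshold in edgeR, with 918 at an unadjusted p under 0.05, and no other tool was run on it. Of the 117 genes, 81 had the same direction in it. Across genes, which are not independent replicates, its log2 fold changes correlated with those of the summed transcript counts at a Pearson r of 0.08. Within a fetus the correlation of the log2 values across genes was 0.621 to 0.644.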
